A study of Mus musculus with 12 samples.

How the data were processed

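Polyadenylated RNA of 12 mouse melanoma cell line samples was sequenced, 3 in each of 4 groups named NTC, Gli2CA, Cas9-NTC and Cas9-Gli2KO. Per the labels, cells grew in DMEM with 10% FBS and puromycin at 1 ug/mL, with blasticidin at 10 ug/mL added in the Cas9 groups, and libraries were made from column-purified RNA with poly(A) selection and an NEBNext Ultra II kit. The values deposited by the authors are FPKM, fragments or reads scaled to gene length and library size, in 1 table of 54532 Ensembl genes and 12 columns. The aligner, counter, annotation, genome build and the use of strand in counting are not given in the sources used here. Genes that overlap others are therefore uncertain, and so are genes with near-identical copies.

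Gene symbols, lengths and coordinates were taken from GENCODE M21 (GRCm38), in which 54495 of the IDs were found, and 28400 genes were at 0 in every library. With M21 lengths, 97.8 to 98.4% of the values of 20 reads or fewer came out as whole reads within 0.02 of a read, which gave the depth of each library. NTC had about 22832500, 16992300 and 16066100 reads, Gli2CA 15972800, 18092200 and 18832500, Cas9-NTC 16946000, 25360200 and 25983200, and the libraries labelled Gli2 knockout 23067700, 22806900 and 23501200. Detection limits were set at 3 reads and intervals are 95% Poisson intervals, which cover counting error only. FPKM sums were 293496 to 407846 per library.

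The test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1) with no further scaling, with a trended prior, on the 11860 genes with at least 1 FPKM in at least 3 of the 12 libraries. All groups entered 1 fit with 8 residual degrees of freedom. Fold changes from the fit are on the log2(FPKM + 1) scale, which understates the change of low genes, while folds in words are ratios of mean FPKM. Calls had a Benjamini-Hochberg adjusted p under 0.05, 2-sided, and calls by at least 2-fold also an absolute log2 change of at least 1. The comparisons were Gli2CA with NTC, the libraries labelled Gli2 knockout with Cas9-NTC, the difference of these changes, the genes called in both with opposite signs, and Cas9-NTC with NTC. A further contrast, the change from NTC to Gli2CA less that from the libraries labelled Gli2 knockout to Cas9-NTC, was added after the results had been seen. Gli2 and Gli1, which lie below the filter, were compared with exact permutation tests, which cannot go below 0.1 for 3 against 3 libraries, and with limma without the filter, and other genes below the filter are given as levels with no test. The permutation tests were run in R. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables and plots.

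There were 24 gene lists with 430 genes in all, of which 18 had at least 5 measured members and were tested with camera at a preset correlation of 0.01 and with Benjamini-Hochberg adjustment over the lists. They covered Hedgehog-GLI targets, Wnt ligands, Wnt feedback targets, prostaglandin genes, myeloid-recruiting factors, chemokines for T cells and dendritic cells, MHC class I genes, interferon-stimulated genes, checkpoint and suppressive factors, melanocyte differentiation, the neural-crest-like state, mesenchymal transition, epithelial genes, collagens and matrix, TGF-beta and BMP signalling, MAPK output, proliferation, hypoxia and glycolysis, p53 targets and the stress response. The last 4 lists were markers of leukocytes, fibroblasts, endothelial cells and keratinocytes. The design, the lists and most of the alternatives were fixed before the data were examined. So was the rule for named genes, which takes Gli2 and 12 pathway and immune genes whatever their test and up to 3 called members of each list with the largest changes. It adds the 5 largest rises and falls without overlap of the libraries, the 5 largest genes with opposite signs in each direction, and the 3 largest either way between the control lines. Predicted and clone-named genes were left out of the last parts, and the filter for them was narrowed after results had been seen, to match the rule as first written, which let AU021092 in. Ribosomal protein genes and the Y-linked genes, Gli3 and the marker genes of the mixture tests were chosen after the data were seen.

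The procedures were tested on simulated data with 200 changed genes among the 11860. For Gli2CA and NTC, 85% and 87.5% of genes changed by -1 and 1 on the log2 scale were recovered, with 16 false calls among 11660 unchanged genes. For the libraries labelled Gli2 knockout and Cas9-NTC, 80% and 97.5% were recovered, with 245 false calls among 11660. A fit of the Cas9 groups alone gave 37 false calls and recovered 21 and 19 of 40 such genes. The bound for an acceptable recovery was lowered after the value of 80% was seen. In the list test, the 1 moved list was found and 0 of 17 unmoved lists were called. The simulated noise was independent between genes, so this test leaves out correlation between list members and cannot give their rate of false calls. In other splits of the real libraries, camera called up to 7 lists for Gli2CA and NTC and up to 4 for the Cas9 groups.

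Alternatives were other pseudocounts (0.1 and 5), filters (5 FPKM, or none beyond being above 0), scaling (rescaling to a common total, median of ratios, quantile normalisation), other variance moderation, library weights, fits of the compared groups alone, an adjusted p under 0.01, fry and an estimated correlation for the lists, a replicate block, and leaving out each library. Library weights were computed gene by gene because the default method did not converge. Added after the data were seen were removal of each library's trend on gene length, voom on the recovered reads of 11856 genes, and a fit without libraries 1 and 2 labelled Gli2 knockout, in which the remaining library is assumed to vary like the other groups. Some items are not reported here.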

Results

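RNA sequencing was carried out on mouse melanoma cells that carry an activated BRAF kinase. The 12 libraries formed 4 groups of 3. In the first experiment, cells labelled as carrying an active form of Gli2 (Gli2CA), a transcription factor of the Hedgehog pathway, were set beside a non-targeted control (NTC). In the second, Cas9 cells labelled as a Gli2 knockout were set beside their own non-targeted control (Cas9-NTC). The comparisons ask which genes follow Gli2 in melanoma cells, with Wnt ligands, prostaglandin genes and immune mediators named as the series' interest. Depth recovered from the values was about 15972800 to 22832500 reads per library in NTC and Gli2CA and 16946000 to 25983200 in the Cas9 groups. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which can be technical. Levels are FPKM, given as mean ± SD over the 3 libraries of a group.

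Gli2 itself (ENSMUSG00000048402, chromosome 1, 118834132 to 119053619, minus strand, GRCm38) was close to undetected in the first experiment. In the second its RNA was higher, not lower, in the libraries labelled Gli2 knockout. NTC had 0 Gli2 reads in each library, which allows up to 0.0272 FPKM in the shallowest, and Gli2CA had 1, 0 and 5 reads. Cas9-NTC had 29, 61 and 42 reads, a level of 0.278 ± 0.0627. The libraries labelled Gli2 knockout had 130, 140 and 345 reads, a level of 1.28 ± 0.74, and each lay above every Cas9-NTC library. The 2-sided exact permutation p was 0.1 for that difference, the smallest that 3 against 3 libraries can give, and 0.4 between Gli2CA and NTC. Without the filter on low values the limma adjusted p was 0.0171 for the former (log2 change 0.79) and 1 for the latter. That fit shares its spread over all groups, and Gli2 was nearly undetected in NTC and Gli2CA. The value of 0.0171 therefore does not measure the spread of the Cas9 groups alone and is too liberal. The labels give neither the sequence of the introduced Gli2 nor the part of the gene that was edited, so RNA level alone does not show the state of the protein. Every direction given for the second experiment is drawn from a label that Gli2 RNA neither bears out nor rules out.

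Gli1 and Ptch1, both known to be induced by Hedgehog signalling, were highest in Gli2CA. Gli1 (ENSMUSG00000025407, chromosome 10, 127329882 to 127341974, minus strand), a transcription factor and direct pathway target, went from 0.189 ± 0.0346 in NTC to 1.19 ± 0.193 in Gli2CA, with an exact permutation p of 0.1, the smallest possible, and a limma adjusted p of 3.48e-05 without the filter on low values (log2 change 0.88). In the Cas9 groups Gli1 lay at 0.0704 ± 0.0238 in Cas9-NTC and 0.101 ± 0.0663 in the libraries labelled Gli2 knockout, with an exact permutation p of 0.7 and a limma adjusted p of 0.803 without that filter. Ptch1 (ENSMUSG00000021466, chromosome 13, 63508328 to 63573598, minus strand), the Hedgehog receptor and a feedback target, rose 2.19-fold to 5.72 ± 0.189 in Gli2CA, a log2 change of 0.90 (SE 0.16, limma adjusted p = 0.00256). It was 1.94, 2.12 and 2.07 in Cas9-NTC and 1.00, 1.08 and 2.32 in libraries 1, 2 and 3 labelled Gli2 knockout (log2 change -0.34, limma adjusted p = 0.114), so library 3 lay above every control library and the other 2 below. Ptch1 was called lower without library 3 (log2 change -0.58, limma adjusted p = 3.03e-05) and with library weights (5.14e-07). Those settings called 7793 and 9158 of 11860 genes in this comparison, so a call under them says little about a single gene. The direction of Ptch1 turned without libraries 1 and 2. Hhip, another feedback target, stayed at or under 0.00406 FPKM in every group mean.

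**Figure D1:**
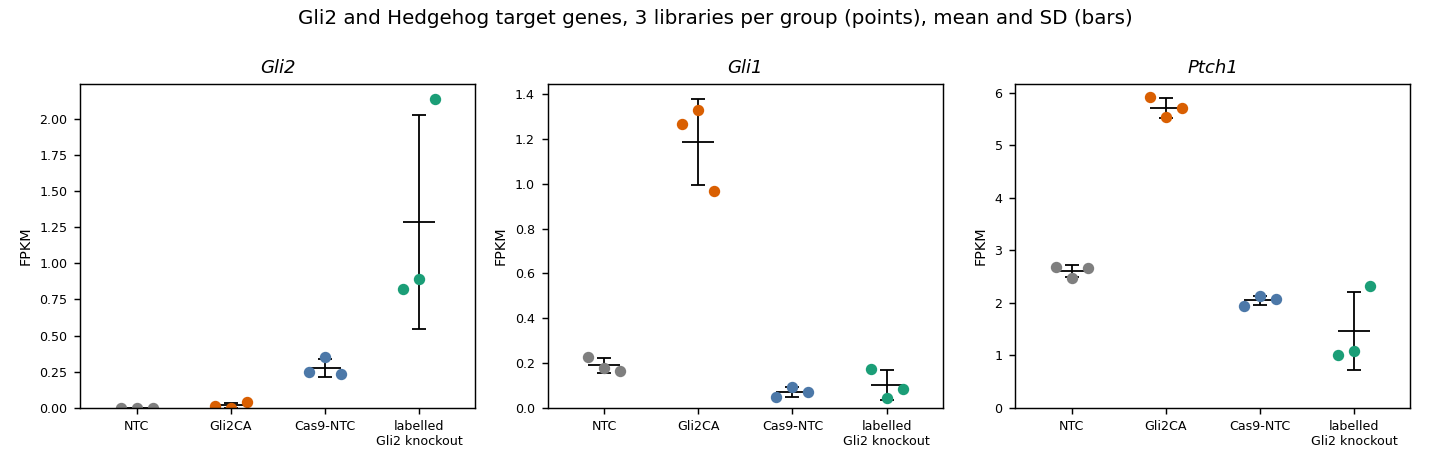
Gli2, Gli1 and Ptch1 in FPKM for each of the 12 libraries (points), with the group mean and SD. Gli2 is highest in the libraries labelled Gli2 knockout (1.28 ± 0.74), and Gli1 and Ptch1 are highest in Gli2CA (1.19 ± 0.193 and 5.72 ± 0.189).

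Against NTC, Gli2CA cells carried more RNA of prostaglandin, myeloid chemokine and hypoxia genes and less RNA of cell cycle genes. Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227, plus strand), which encodes an inducible cyclooxygenase, rose 7.52-fold from 13.4 ± 1.73 to 101 ± 7.58. The prostaglandin transporter Slco2a1 (ENSMUSG00000032548, chromosome 9, 102988712 to 103096002, plus strand) rose from 0.253 ± 0.0677 to 24.9 ± 1.33. On the log2(FPKM + 1) scale, the largest rises among genes that the naming rule admits also held Pdpn (ENSMUSG00000028583, chromosome 4, 143267431 to 143299564, minus strand), the membrane glycoprotein podoplanin, at 27.1-fold to 50.9 ± 3.87. The BMP antagonist Grem1 rose 12.4-fold to 117 ± 6.99 and the metallothionein Mt1 31.1-fold to 8.87 ± 0.918. Fxyd2, a regulator of the sodium pump, was listed at 0 in every NTC library and reached 9.66 ± 0.839. The largest falls on that scale, under the same rule, were those of Tmem98, 18.6-fold from 11.7 ± 1.36, Shisa2, 4.77-fold from 15 ± 0.581, AU021092, 5.73-fold, the metalloprotease Adam12, 5.36-fold, and Sntb1, 4.92-fold.

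Of the 8 measured genes of prostaglandin synthesis, transport and receptors, 5 rose, 0 fell and 3 were not called, and 5 rose and 1 fell adjusted over the list alone. Ptgs2 had a log2 change of 2.83 (SE 0.10, limma adjusted p = 2.6e-08) and Slco2a1 one of 4.37 (SE 0.22, limma adjusted p = 4.24e-07). Ptgs1, the constitutive cyclooxygenase, rose 2.05-fold to 92.4 ± 6.22, and Ptges, a prostaglandin E synthase, went from 0.0502 ± 0.0736 to 0.743 ± 0.0585 (log2 change 0.73, limma adjusted p = 0.000337). The list was higher with a median log2 change of 0.73 (camera adjusted p = 2.99e-05). Of 8 measured myeloid-recruiting chemokines and cytokines, 5 rose, 0 fell and 3 were not called, with the same 5 and 0 adjusted over the list alone (median 1.09, camera adjusted p = 2.99e-05). Ccl2 (ENSMUSG00000035385, chromosome 11, 82035571 to 82037453, plus strand), a monocyte chemoattractant, rose 2.87-fold to 639 ± 20.5, and its neighbour Ccl7 2.88-fold to 154 ± 2.16. Ccl8 rose 11.2-fold to 11.5 ± 0.79, and S100a8, a myeloid alarmin, 8.63-fold to 13.1 ± 1.28. The neutrophil chemokine Cxcl1 was 13.4 ± 0.717 in NTC and 14.8 ± 2.11 in Gli2CA (log2 change 0.13, limma adjusted p = 0.657), while Cxcl2 and Cxcl5 averaged under 0.06 FPKM in both groups.

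Of 16 measured hypoxia and glycolysis genes, 11 rose, 0 fell and 5 were not called, and 15 rose adjusted over the list alone (median 0.65, camera adjusted p = 4.04e-10). Ndrg1, a hypoxia-inducible gene, rose 2.56-fold, the glucose transporter Slc2a1 2.01-fold from 56.0 ± 4.34 to 113 ± 2.46, and the hexokinase Hk2 2.65-fold, although the call of Hk2 ended when libraries were rescaled to a common total (limma adjusted p = 0.0537). Ankrd37, which partly overlaps other genes, was also called higher. That call ended with a pseudocount of 0.1 (limma adjusted p = 0.0515), without the filter on low values (0.103) and with quantile normalisation (0.0571). Its range went up to 0.155. Of 22 measured proliferation genes, 13 fell, 0 rose and 9 were not called, and 18 fell and 1 rose adjusted over the list alone (median -0.50, camera adjusted p = 2.48e-10). The cyclin Ccna2, part of which overlaps another gene, fell 1.69-fold to 24.0 ± 0.551, the mitotic activator Cdc20 1.66-fold to 33.1 ± 2.48, and the replication helicase subunit Mcm6 1.66-fold to 14.7 ± 0.709.

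Of 6 measured Wnt ligands, 2 rose, 0 fell and 4 were not called, and 3 rose adjusted over the list alone. Wnt7a (ENSMUSG00000030093, chromosome 6, 91363981 to 91411363, minus strand) rose 4.61-fold from 2.67 ± 0.138 to 12.3 ± 0.972, and Wnt2 8.72-fold to 2.40 ± 0.202. Wnt5a averaged 0.0209 ± 0.0164 in NTC and 0.257 ± 0.0308 in Gli2CA (limma adjusted p = 0.188). It was called with a pseudocount of 0.1 (limma adjusted p = 0.00098), in a fit of these groups alone (0.00617), with library weights (0.00494) and with voom (0.0132), in a range up to 0.669. Wnt7b averaged 0.0246 ± 0.0214 and 0.231 ± 0.0554 (limma adjusted p = 0.526), and the first 3 of these settings called it (0.00358, 0.0161 and 0.0196), in a range up to 0.921. Wnt11 was at 0.00706 ± 0.0122 and 0.123 ± 0.0558, below the level tested. The Wnt ligand list was higher (median 0.37, camera adjusted p = 0.00156; adjusted p = 0.0947 with an estimated correlation, range over its alternatives 3.13e-06 to 0.0947). Of 9 measured Wnt feedback targets, 3 rose, 1 fell and 5 were not called, with the same counts adjusted over the list alone (camera adjusted p = 0.105, and 0.0447 with the length trend removed, range over its alternatives up to 0.445). The stem cell receptor Lgr6 rose 2.58-fold and Tnfrsf19 2.09-fold, and the transcription factor Lef1, part of which overlaps an antisense gene, fell 9.62-fold from 1.5 ± 0.097.

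Of 17 measured genes of MHC class I antigen presentation, 5 rose, 0 fell and 12 were not called, with the same counts adjusted over the list alone (median 0.13, camera adjusted p = 0.00588; adjusted p = 0.0426 with an estimated correlation). Quantile normalisation ended that call (camera adjusted p = 0.102, range over its alternatives 2.87e-06 to 0.102). The class I heavy chains H2-K1 and H2-D1, whose reads can be shared with near-identical family members, rose 3.43-fold to 22.1 ± 0.879 and 2.21-fold to 101 ± 2.87. Of 22 measured interferon-stimulated genes, 3 rose, 0 fell and 19 were not called, the same adjusted over the list alone. The antiviral enzyme gene Oas1a was listed at 0 in every NTC library and reached 1.77 ± 0.2. The other calls, Ifit3 (limma adjusted p = 0.0318) and Ifit1 (0.0125), both ended with a pseudocount of 5 (0.0822 and 0.344) and without Gli2CA library 3 (0.138 and 0.0535). That of Ifit3 also ended without NTC library 1 (0.0749) or 3 (0.116), without Gli2CA library 1 (0.104), without the filter on low values (0.0546), after rescaling (0.128), with the length trend removed (0.0603) and with voom (0.139), in a range from 0.00118. That of Ifit1 ended without Gli2CA library 2 (0.0516) and with quantile normalisation (0.243), in a range from 6.36e-05. The interferon list was higher (median 0.17, camera adjusted p = 0.00597; adjusted p = 0.307 with an estimated correlation, the top of its range from 1.38e-05), and its call also ended with a pseudocount of 5 (camera adjusted p = 0.102) and with quantile normalisation (camera adjusted p = 0.0821). Of 4 measured chemokines that recruit T cells and dendritic cells, Ccl5 rose from 0.191 ± 0.195 to 2.91 ± 0.908, Cxcl10 fell 1.72-fold to 1.72 ± 0.269 and 2 were not called, with 1 higher and 2 lower adjusted over the list alone. The median of these 4 was -0.23 and the mean 0.17, and the list was too small for the set test. Of 10 measured checkpoint ligands and suppressive factors, 3 rose, 1 fell and 6 were not called, the same adjusted over the list alone (camera adjusted p = 0.196). This list was called higher without the filter on low values (camera adjusted p = 0.00673) and by fry (0.000157), in a range up to 0.354. The ectonucleotidase Nt5e rose 1.89-fold to 16.6 ± 0.498, the immunoglobulin family member Vsir rose to 0.712 ± 0.0854 and the adhesion ligand Pvr rose 1.58-fold. Cd274, which encodes PD-L1 and partly overlaps an antisense gene, was below the level tested at 0.141 ± 0.0516 in NTC and 0.26 ± 0.177 in Gli2CA.

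Of 20 measured genes of mesenchymal transition, 5 rose, 0 fell and 15 were not called, and 7 rose adjusted over the list alone. The matrix protein Tnc rose 3.26-fold and the matrix protein Tgfbi 1.90-fold, although rescaling to a common total ended the Tgfbi call (limma adjusted p = 0.0591). The list was higher (median 0.26, camera adjusted p = 0.000843; adjusted p = 0.307 with an estimated correlation, range over its alternatives 1.83e-05 to 0.307). Of 16 measured genes of MAPK pathway output, 7 rose, 1 fell and 8 were not called, the same adjusted over the list alone (median 0.27, camera adjusted p = 0.000843; adjusted p = 0.354 with an estimated correlation, range 8.78e-05 to 0.354). The early response gene Egr1 rose 2.52-fold, and Dusp5 2.48-fold while Spry1 fell 2.28-fold. Both of the latter are feedback inhibitors and partly overlap other genes. Of 5 measured melanocyte differentiation genes, 2 fell, 0 rose and 3 were not called, and 3 fell adjusted over the list alone. Rab38, which serves melanosome transport, fell 3.97-fold and the glycoprotein gene Gpnmb 2.04-fold. That list was lower (median -0.21, camera adjusted p = 0.0139; adjusted p = 0.0791 with an estimated correlation), and its call ended without the filter on low values (camera adjusted p = 0.511, range over its alternatives 9.59e-05 to 0.511).

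The other lists were not called by camera in Gli2CA. Of 11 Hedgehog-GLI targets, 5 rose and 2 fell, and 6 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.316), among them Ptch1 and the forkhead factor Foxl1, up 2.38-fold. This list was called higher without the filter on low values (camera adjusted p = 0.00673) and by fry (0.00877), in a range over its alternatives up to 0.386. Of 13 neural-crest-like genes, 3 rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 0.0519, and called with 0.0191 without Gli2CA library 2, 0.021 without the filter on low values, 0.0397 with a pseudocount of 5, 0.0246 in a fit of these groups alone, 0.0267 with library weights, 0.0477 with the length trend removed and 0.0376 with voom, range over its alternatives 0.0191 to 0.459), with Sox9, a neural crest transcription factor, up 2.38-fold and the lysyl oxidase Loxl2 up 2.13-fold. Of 16 TGF-beta and BMP genes, 2 rose and 5 fell, the same adjusted over the list alone (camera adjusted p = 0.222), with a median of -0.17, a mean of 0.04 and a test direction of lower. In this list the ligand Bmp2 rose 2.70-fold with Grem1, and Id3, a target of BMP signalling, fell 2.74-fold from 38.4 ± 3.1 to 14.0 ± 2.04. Of 16 collagen and matrix genes, 2 rose and 2 fell, and 3 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.773). Of 16 p53 targets, 3 rose and 2 fell, and 4 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.742), with the kinase gene Plk2 up 1.87-fold. Of 18 genes of the integrated stress and unfolded protein response, 4 rose and 1 fell, and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.33), with the transcription factor Ddit3 up 2.11-fold. Among markers of other cell types, the lysosomal protein Cd68 was the 1 leukocyte marker measured and rose 4.96-fold, both measured epithelial genes rose with the keratin Krt19 up 5.51-fold, and the VEGF receptor Flt1 rose 4.33-fold as 1 of 2 measured endothelial markers. These lists had 14, 18 and 12 members, so most members lay below the filter. Of 3 fibroblast markers 1 rose and of 4 keratinocyte markers 2 rose, 3 adjusted over the list alone, while the other marker counts were the same adjusted over the list alone. The fibroblast call, Pdgfra, ended after rescaling (limma adjusted p = 0.0764, range from 3.17e-05). The keratinocyte call of Ivl (0.0276) ended with a pseudocount of 5 (0.118), with quantile normalisation (0.223), with the length trend removed (0.113), and without NTC library 1 or 2 or Gli2CA library 1 or 3 (0.0751 to 0.112), in a range from 0.00355.

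Limma called 1685 of 11860 genes between Gli2CA and NTC, 1002 higher and 683 lower, and 275 by at least 2-fold, 237 higher and 38 lower. The groups did not overlap at 43.7% of genes, where chance gives 10%. The share of higher calls was 59.5%, and it was 34.6% after rescaling to a common total, which moved the median of all genes from 0.00 to -0.14, and 44.9% with voom. Among 2-fold calls the share was 86.2%, and 72.8% and 75.5% under these settings.

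**Figure D2:**
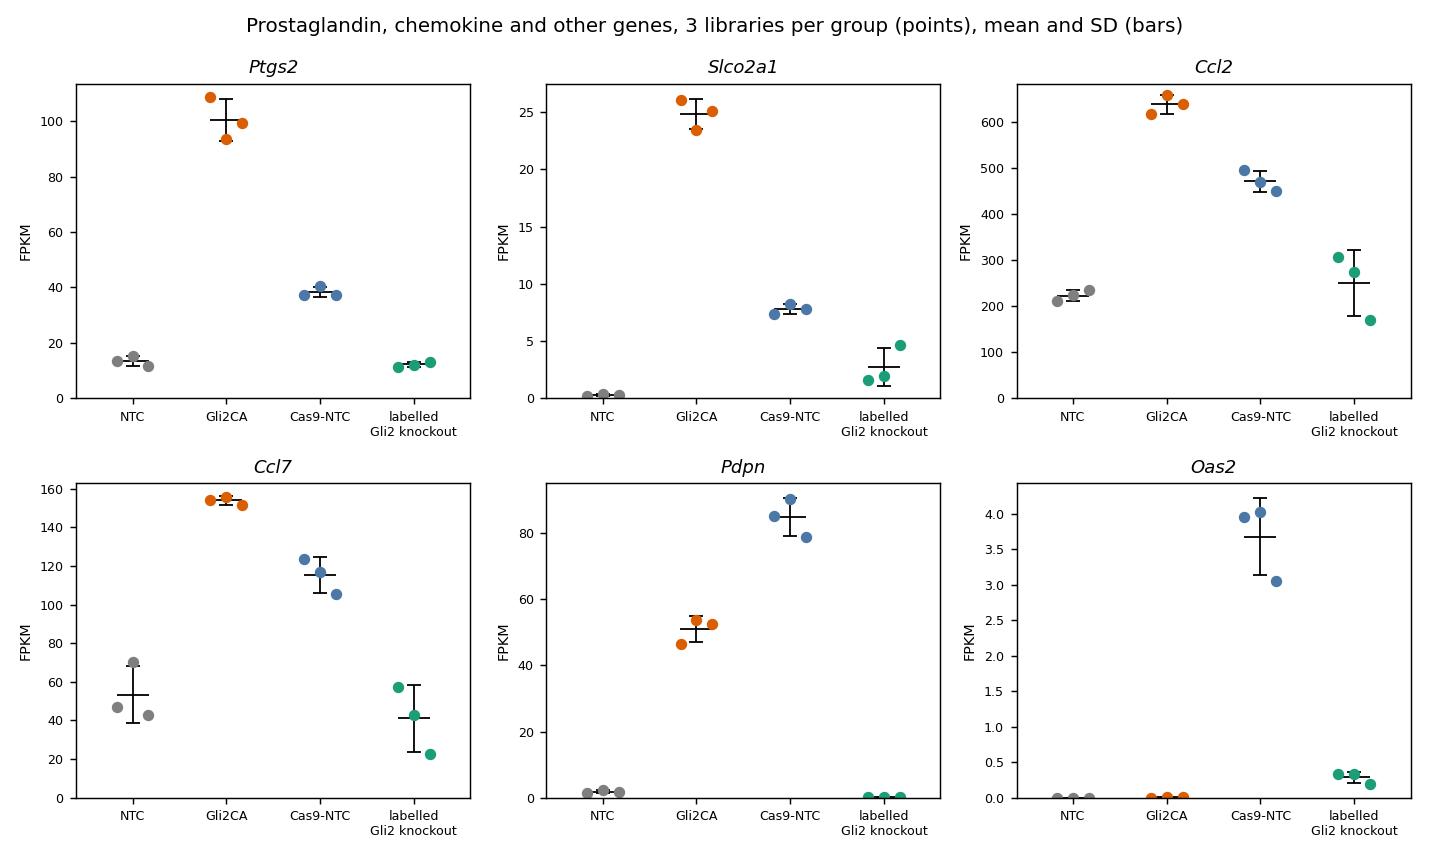
Ptgs2, Slco2a1, Ccl2, Ccl7, Pdpn and Oas2 in FPKM for each of the 12 libraries (points), with the group mean and SD. The first 5 are higher in Gli2CA than in NTC and lower in the libraries labelled Gli2 knockout than in Cas9-NTC, and Oas2 falls from 3.68 ± 0.54 to 0.286 ± 0.0819 in the Cas9 groups.

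Against Cas9-NTC, the libraries labelled Gli2 knockout had lower levels of Pdpn, Ptgs2 and Oas2, although their Gli2 RNA was higher. Pdpn fell 532-fold from 84.7 ± 5.7 to 0.159 ± 0.0751. Ptgs2 fell 3.14-fold from 38.3 ± 1.91 to 12.2 ± 0.922, and the antiviral enzyme gene Oas2 12.9-fold from 3.68 ± 0.54. Other large falls were those of Gldn, 25.4-fold from 16.5 ± 0.593, the small chaperone Hspb8, 16.1-fold, the prolactin family gene Prl2c3, 13.2-fold with reads that near-identical copies can share, and the costimulatory receptor Tnfrsf9, 12.3-fold. On the log2(FPKM + 1) scale, the largest rises under the naming rule were those of Cox7b2, from 0.168 ± 0.0428 to 11.4 ± 5.82, the tetraspanin Tspan6, 9.74-fold, Prelid2, 8.08-fold, Xlr, from 0.131 ± 0.0463 to 3.55 ± 1.98 within a family of near-identical copies, and the phosphatase inhibitor Ppp1r1a, 4.64-fold.

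Library 3 labelled Gli2 knockout stood apart from libraries 1 and 2. Its distance from the mean of the other members of its group was 0.58 (root mean square, log2), against 0.42 and 0.25 for libraries 1 and 2 and 0.16 to 0.28 in the other groups. Libraries 1 and 2 held more RNA of short genes, with slopes of -0.188 and -0.140 log2 units per doubling of gene length against 0.030 in library 3. The median of 78 ribosomal protein genes was 789 and 640 FPKM in libraries 1 and 2 and 350 in library 3, and 15 of the 78 rose in the group (median log2 change 0.59). Rescaling to a common total moved the median of all genes to -0.17 in this comparison.

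**Figure D3:**
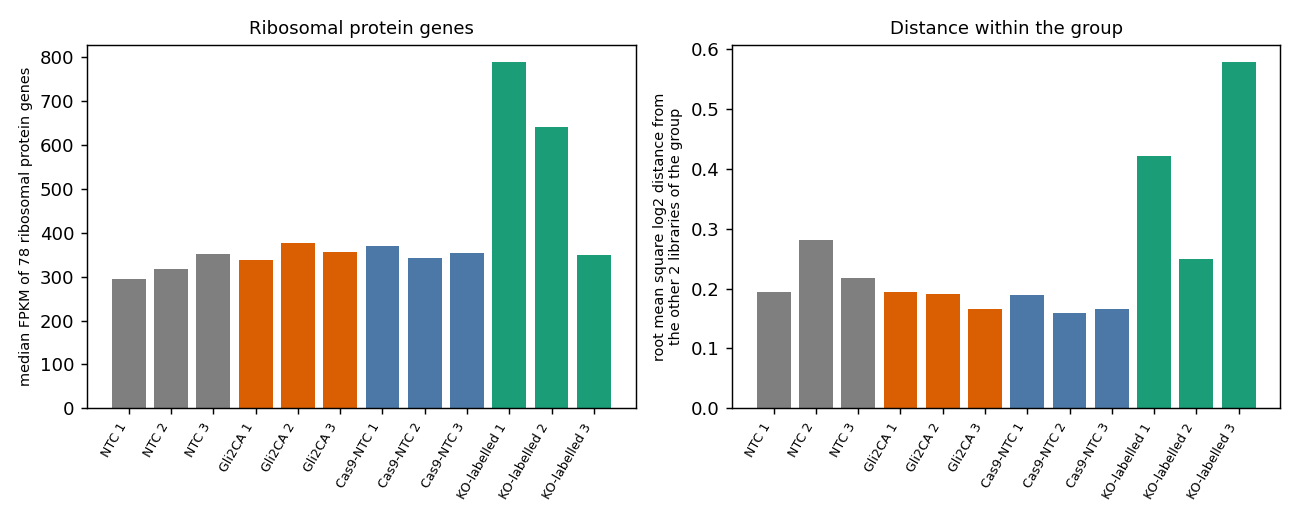
Median FPKM of 78 ribosomal protein genes in each library, and each library's root mean square log2 distance from the mean of the other libraries of its group. Libraries 1 and 2 labelled Gli2 knockout have the highest medians (789 and 640 FPKM), and library 3 of that group has the largest distance (0.58).

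Of 22 measured interferon-stimulated genes, 19 fell in the libraries labelled Gli2 knockout, 0 rose and 3 were not called, the same adjusted over the list alone. Oas2 had a log2 change of -1.86 (SE 0.10, limma adjusted p = 9.01e-07), the interferon regulatory factor Irf7 fell 2.66-fold to 3.25 ± 0.188, and Ddx58, which encodes the RNA sensor RIG-I, 2.79-fold to 3.35 ± 1.49. The list was lower (median -0.79, camera adjusted p = 5.41e-12; adjusted p = 0.0789 with an estimated correlation, range over its alternatives 7.42e-19 to 0.0789). Of 8 prostaglandin genes, 6 fell, 0 rose and 2 were not called, and 6 fell and 1 rose adjusted over the list alone. Ptgs2 had a log2 change of -1.58 (SE 0.10, limma adjusted p = 4.76e-06), Ptgs1 fell 1.76-fold to 37.2 ± 8.45, and Ptges 1.94-fold to 1.65 ± 0.127. Slco2a1 fell 2.86-fold to 2.73 ± 1.68 (log2 change -1.33, limma adjusted p = 0.00224), with a log2 change of -0.64 without libraries 1 and 2 and a limma adjusted p of 0.061 in a fit of the Cas9 groups alone. The prostaglandin list was lower (median -0.74, camera adjusted p = 0.00678; adjusted p = 0.0882 with an estimated correlation, range over its alternatives 4.52e-06 to 0.0882), and its call ended with library weights (camera adjusted p = 0.0644) and without library 3 (camera adjusted p = 0.0516).

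Of 8 myeloid-recruiting factors, 5 fell, 0 rose and 3 were not called, the same adjusted over the list alone. Ccl2 fell 1.89-fold from 471 ± 22.9 to 250 ± 72.4, Ccl7 (ENSMUSG00000035373, chromosome 11, 82045712 to 82047525, plus strand) 2.81-fold to 41.0 ± 17.4, and the cytokine Lif 3.26-fold to 1.46 ± 0.319. In a fit of the Cas9 groups alone Ccl2 and Ccl7 had limma adjusted p values of 0.077 and 0.0506. The list was lower (median -0.50, camera adjusted p = 0.0316; adjusted p = 0.16 with an estimated correlation, range over its alternatives 0.000108 to 0.16). Its call ended without Cas9-NTC library 1 (camera adjusted p = 0.0593), without library 3 labelled Gli2 knockout (0.13), with library weights (0.0644), without the filter on low values (0.0933) and with a filter of 5 FPKM (0.153). Cxcl1 was 0.535 ± 0.0273 in Cas9-NTC and 0.354 ± 0.298 in the libraries labelled Gli2 knockout (limma adjusted p = 0.279). It was called lower without library 1 of the latter group (limma adjusted p = 0.0483), with the length trend removed (0.0383) and with library weights (0.00115), in a range up to 0.691. The fit with library weights called 9158 of 11860 genes in this comparison. Cd274 was 0.709 ± 0.0972 and 0.478 ± 0.25, below the level tested.

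Of 16 genes of MAPK output, 8 fell, 1 rose and 7 were not called, and 10 fell and 1 rose adjusted over the list alone. Ier3, an early response gene, fell 2.06-fold to 119 ± 11.1, Dusp5 2.17-fold and Egr1 2.20-fold, while Spry1 rose 1.79-fold. The list was lower (median -0.53, camera adjusted p = 0.00114; adjusted p = 0.434 with an estimated correlation, range over its alternatives 6.68e-06 to 0.434), and its call ended without libraries 1 and 2 (camera adjusted p = 0.252). Of 16 collagen and matrix genes, 6 fell, 0 rose and 10 were not called, and 8 fell adjusted over the list alone. The collagen Col6a2 fell 2.59-fold to 5.09 ± 2.75, with a log2 change of -1.31, -0.62 without libraries 1 and 2, and a limma adjusted p of 0.0645 in a fit of the Cas9 groups alone. Col6a1 and Col18a1 had the next largest log2 changes among called members (-0.99 and -0.98). Both calls ended in a fit of the Cas9 groups alone (limma adjusted p = 0.144 and 0.179). The matrix protein Thbs1 fell 2.34-fold to 1.73 ± 0.92. This list was lower (median -0.68, camera adjusted p = 0.0104; adjusted p = 0.568 with an estimated correlation, range over its alternatives 6.55e-05 to 0.568), its call ended with fry (adjusted p = 0.104), and its direction turned without libraries 1 and 2 (camera adjusted p = 0.252). Libraries 1 and 2 held less RNA of long genes, and the group's median log2 change ran from 0.35 in the shortest of 10 length classes to -0.18 in the longest. With that trend removed both lists were still called (camera adjusted p = 0.00103 for MAPK output and 0.0478 for collagens).

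The other lists were not called by camera in this comparison, while fry, which does not set a list against other genes, called 11 lists in all. Of 6 Wnt ligands, Wnt5b fell 1.70-fold to 1.49 ± 0.219 and 5 were not called (camera adjusted p = 0.212). Wnt5a was 2.46, 2.52 and 2.32 in Cas9-NTC and 1.66, 1.38 and 2.70 in libraries 1, 2 and 3 labelled Gli2 knockout (log2 change -0.26, limma adjusted p = 0.15), so library 3 lay above every control library and the other 2 below. It was called lower without library 3 of the latter group (log2 change -0.45, limma adjusted p = 0.000816) and with library weights (3.92e-06), and its direction turned without libraries 1 and 2 (0.552, the top of its range). Wnt7a was listed at 0 in every Cas9 library. Wnt7b was 71.3, 76.5 and 78.7 in Cas9-NTC and 44.2, 53.7 and 98.8 in libraries 1, 2 and 3 labelled Gli2 knockout, a log2 change of -0.28 (limma adjusted p = 0.326). That change was -0.62 without library 3 (limma adjusted p = 8.79e-05) and 0.39 without libraries 1 and 2. Wnt7b was called lower with library weights (limma adjusted p = 6.31e-06), in a range up to 0.895. The fit without library 3 called 7793 of 11860 genes and the fit with library weights 9158. Calls of Wnt5a and Wnt7b under these settings therefore say little about these genes. Of 16 hypoxia and glycolysis genes, 6 fell and 0 rose (camera adjusted p = 0.0676), with the carbonic anhydrase Car9 down 6.6-fold and Slc2a1 down 1.88-fold. That list was called lower without library 1 (camera adjusted p = 0.012), without library 2 (0.0286) and without both (0.000122), without the filter on low values (0.00841), with quantile normalisation (0.00951), after rescaling (0.0473), with the length trend removed (0.0348) and by fry, with a range over its alternatives of 0.000121 to 0.489. Of 20 mesenchymal genes, 7 fell and 3 rose, and 9 fell and 3 rose adjusted over the list alone (camera adjusted p = 0.0676, and called with 0.0159 without library 3, 0.00841 without the filter on low values, 0.0454 with a pseudocount of 0.1, 0.0441 with quantile normalisation and 0.0423 with library weights, range over its alternatives 0.00841 to 0.935), with Tgfbi down 2.70-fold, the homeobox gene Prrx2 up 3.02-fold and the protease Mmp9 up 6.36-fold. Of 17 MHC class I genes, 5 fell and 0 rose (camera adjusted p = 0.17), with the nonclassical H2-T23 down 2.11-fold. Of 13 neural-crest-like genes, 4 fell and 1 rose (camera adjusted p = 0.17, and 0.0348 without library 3, range over its alternatives 0.0348 to 0.606). Of 22 proliferation genes, 5 rose and 0 fell (camera adjusted p = 0.212, and 0.000857 without libraries 1 and 2, range over its alternatives 0.000857 to 0.772).

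Of 11 Hedgehog-GLI targets, 1 fell, the growth factor binding protein Igfbp6, 2.68-fold to 2.58 ± 0.549 (camera adjusted p = 0.201, and 0.00659 by fry, range over its alternatives up to 0.935). Of 10 checkpoint and suppressive factors, 4 fell and 1 rose, with Pvr down 1.85-fold (camera adjusted p = 0.102, and 0.00144 without the filter on low values, range over its alternatives 0.00021 to 0.328). Of 9 Wnt feedback targets, Nkd2 rose 1.70-fold and 8 were not called (camera adjusted p = 0.952), and of 5 melanocyte genes Gpnmb was called lower (camera adjusted p = 0.473). The Gpnmb call (limma adjusted p = 0.0169) ended in a fit of the Cas9 groups alone (0.124), without libraries 1 and 2 (0.162), without library 2 labelled Gli2 knockout (0.067) and without any single Cas9-NTC library (0.0521 to 0.0552), in a range from 1.53e-07. Of 16 TGF-beta and BMP genes, 4 rose and 4 fell, and 5 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.831), with Id3 up 2.17-fold to 42.2 ± 9.85 and Grem1 down 1.89-fold to 62.8 ± 9.94. Of 16 p53 targets, 2 rose and 4 fell (camera adjusted p = 0.952), with a median of 0.03 and a mean of -0.03, and of 18 stress response genes 1 rose and 5 fell, 2 and 5 adjusted over the list alone (camera adjusted p = 0.473), with Chac1 down 2.24-fold. Of the lists too small for the set test, 1 of 4 T-cell chemokines was called lower, Ccl5, 1 of 2 epithelial genes was, the keratin Krt18, Cd68 fell 5.37-fold, and 2 of 4 keratinocyte markers fell, with the lectin Lgals7 down 4.22-fold. The fibroblast markers Dpt and Pdgfra fell 3.02-fold and 3.09-fold while Fap rose 2.86-fold, and of 2 endothelial markers Flt1 fell 2.36-fold and Cdh5 rose to 11.4 ± 6.94, both calls being lost in a fit of the Cas9 groups alone. The call of Ccl5 (limma adjusted p = 0.0413) ended with a pseudocount of 0.1 (0.338), without the filter on low values (0.0895), after rescaling (0.0609), with quantile normalisation (0.0695), in a fit of the Cas9 groups alone (0.059), without libraries 1 and 2 (0.0816) and without any single library of these groups but library 3 labelled Gli2 knockout (0.069 to 0.116). That of Krt18 (0.018) ended with a pseudocount of 0.1 (0.151), with voom (0.0554), without libraries 1 and 2 (0.223), and without Cas9-NTC library 1 or 2 or library 1 or 2 labelled Gli2 knockout (0.0615 to 0.067). Their ranges were 0.00121 to 0.338 and 0.000107 to 0.223. Where no other count is given, the counts were the same adjusted over the list alone.

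Limma called 3182 of 11860 genes between the libraries labelled Gli2 knockout and Cas9-NTC, 1323 higher and 1859 lower, and 333 by at least 2-fold, 134 higher and 199 lower. In simulated data for this comparison the same fit made 245 false calls among 11660 unchanged genes, and a fit of the Cas9 groups alone made 37, so the adjusted p values and counts of called list members given here are too liberal. The groups did not overlap at 34.9% of genes, where chance gives 10%. Without library 3 labelled Gli2 knockout the counts were 7793 and 1024, without libraries 1 and 2 1595 and 234, and without library 1 or 2 singly 1643 or 1338. Without Cas9-NTC library 1, 2 or 3 the first count was 1693, 1447 or 1479, and a fit of the Cas9 groups alone called 762. The share of higher genes among 2-fold calls was 40.2%, and it ran from 19.8% after rescaling to a common total and 22.8% after removal of the length trend to 52.6% with library weights and 54.5% without library 3, so the excess of falls turned in the last 2 settings.

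The experiments tended to move genes in opposite directions, with the second direction drawn from the label. Of 716 genes called in both, 620 had opposite signs and 96 the same sign, where independent lists would share 233 and 219. The calls of the second experiment come from the fit that was too liberal in simulated data. A fit of the Cas9 groups alone called 762 genes, and opposite signs were not counted with those. In all, 460 genes were higher in Gli2CA and lower in the libraries labelled Gli2 knockout, against 157 for independent lists, and 160 were lower and then higher, against 76.2. Besides Pdpn and Prl2c3, the first group held Slfn2, a regulator of lymphocyte quiescence (log2 changes 1.85 and -1.94), Cd68 (1.75 and -1.92) and the adhesion molecule Sele (1.73 and -1.59). The second held the lactate dehydrogenase subunit Ldhb (-1.26 and 1.38), Id3 (-1.40 and 1.05) and the protease Prss23 (-0.86 and 1.03), which partly overlaps another gene. It also held Gulp1 and Slc35g1, whose calls were lost without libraries 1 and 2 labelled Gli2 knockout. Across genes, which are not independent replicates, the log2 changes had a Pearson r of -0.28 and a Spearman rho of -0.29. The 460 and 160 genes became 305 and 219 after rescaling to a common total, 370 and 226 with quantile normalisation, and 380 and 251 with voom. Left out singly, Gli2CA library 1 or 3 gave 411 or 410 opposite genes, Cas9-NTC library 2 or 3 gave 389 or 402, library 2 labelled Gli2 knockout 411, and library 3 1770 beside 671 of the same sign.

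**Figure D4:**
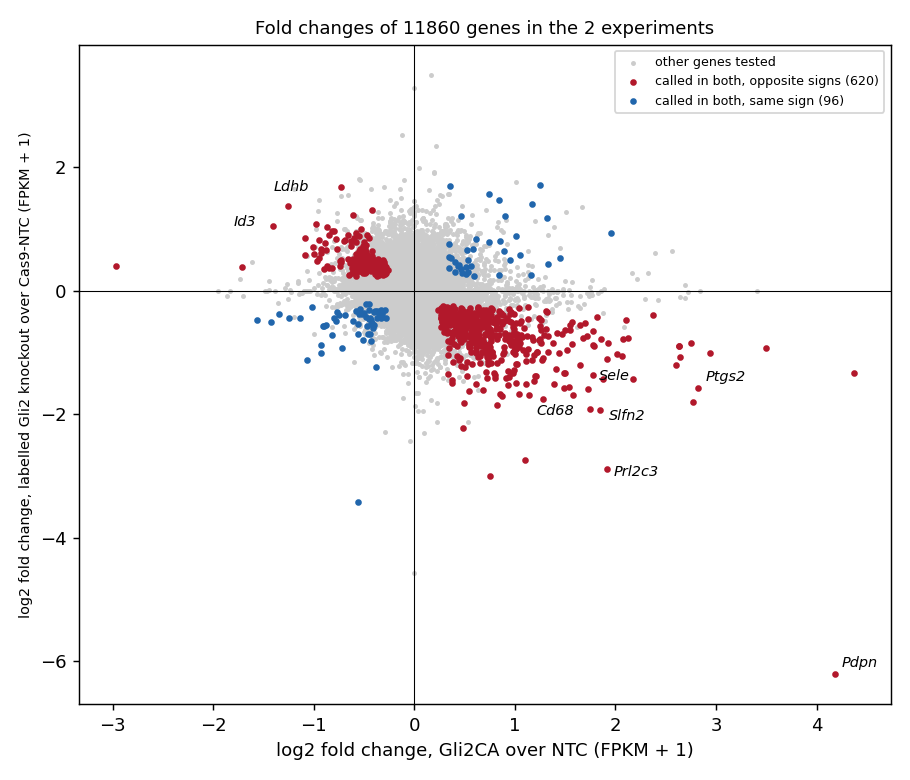
Log2 change of each tested gene in Gli2CA against NTC (horizontal) and in the libraries labelled Gli2 knockout against Cas9-NTC (vertical). Genes called in both comparisons are marked, 620 with opposite signs and 96 with the same sign.

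The test of the difference between the changes asks which genes responded otherwise in Gli2CA than in the libraries labelled Gli2 knockout. At the gene level it called 3356, 1976 higher and 1380 lower in limma, and 7535 without library 3 labelled Gli2 knockout. It rests on the same shared fit, and its rate of false calls was not simulated. The share of higher calls was 58.9%, 47.1% after rescaling to a common total and 48.8% with voom. Camera called 12 lists. Interferon-stimulated genes (camera adjusted p = 3.58e-10), hypoxia and glycolysis (1.56e-06), myeloid-recruiting factors (5.44e-05) and prostaglandin genes (0.000234) had higher changes in Gli2CA, and proliferation genes lower ones (4.28e-06). With an estimated correlation the adjusted p values were 0.0248, 0.00911, 0.0157, 0.0157 and 0.0157 in that order. The other 7 lists also had higher changes in Gli2CA, and their calls were lost with an estimated correlation. They were MAPK output (camera adjusted p = 7.03e-05, then 0.273), Wnt ligands (0.00126, then 0.0886), mesenchymal transition (0.00758, then 0.385), neural-crest-like genes (0.0104, then 0.401), MHC class I (0.0134, then 0.0614), checkpoint factors (0.0487, then 0.195) and collagens (0.0487, then 0.651).

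The control lines themselves were far apart. Their libraries correlated at 0.835 to 0.843 with each other, against 0.968 to 0.978 between NTC and Gli2CA. Cas9, blasticidin, culture history and any other difference between the lines cannot be separated in that comparison. The interferon-stimulated genes were higher in Cas9-NTC than in NTC at 22 of 22 measured members, the same adjusted over the list alone (median 2.05, camera adjusted p = 7.4e-15; adjusted p = 0.0211 with an estimated correlation). Among measured markers of other cell types, 3 of 3 fibroblast genes (median 2.80), 2 of 2 endothelial genes (median 1.25), the 1 leukocyte gene, Cd68 (2.08), and 1 of 2 epithelial genes were higher there. Of 4 keratinocyte genes 1 was higher and 2 lower, and all counts were the same adjusted over the list alone. These lists had 12, 12, 14, 18 and 12 members in that order, so most members lay below the filter. A gene can pass the filter through the Cas9 libraries alone, which favours higher counts in Cas9-NTC. The counts therefore do not show a likeness to another cell type. Of 17 MHC class I genes, 13 were higher and 2 lower, and 14 and 2 adjusted over the list alone (camera adjusted p = 6.7e-05; adjusted p = 0.0211 with an estimated correlation). Mt1 was at 161 ± 3.38 in Cas9-NTC and 0.285 ± 0.0954 in NTC, and the homeobox gene Rhox5 at 129 ± 1.54 and 0.0781 ± 0.135. Trp53i11 lay at 212 ± 5.2 and 0.0112 ± 0.0195. In the other direction, the endopeptidase gene Ecel1 was at 0.142 ± 0.111 in Cas9-NTC and 752 ± 99.4 in NTC, the protease inhibitor Serpina3n at 1.00 ± 0.0763 and 532 ± 28.4, and the microtubule protein Tppp3 at 0.565 ± 0.177 and 422 ± 23.1. Limma called 5798 genes, 2841 higher and 2957 lower in Cas9-NTC, and with voom the median of all genes lay at 0.12. Prostaglandin (camera adjusted p = 0.00583), proliferation (0.0216) and hypoxia genes (0.0306) were also higher in Cas9-NTC, and neural-crest-like (0.00583), collagen (0.0243) and stress response genes (0.0243) lower. With an estimated correlation those calls ended at adjusted p = 0.0593, 0.168, 0.132, 0.41, 0.641 and 0.183 in that order.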

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

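The contrast between the lines and all tests of explanations here were chosen after the results had been seen, while the counts over other splits of the libraries were planned.

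The change from NTC to Gli2CA was set against the change from the libraries labelled Gli2 knockout to Cas9-NTC, to see where the lines differ in what a label of more Gli2 goes with. Limma called 1246 genes for this difference, 574 higher and 672 lower in the first line, with 1390 after removal of the length trend, 6671 without library 3 labelled Gli2 knockout and 1589 without libraries 1 and 2. By camera 5 lists differed, and with an estimated correlation none passed an adjusted p of 0.05. Interferon-stimulated genes had medians of 0.17 and 0.79 in the lines (camera adjusted p = 1.12e-07, adjusted p = 0.0846 with an estimated correlation). All 22 of them were lower in NTC than in Cas9-NTC, and the log2(FPKM + 1) scale understates changes of low genes. Part of that difference can therefore come from the starting level. Proliferation genes had medians of -0.50 and -0.04 (camera adjusted p = 0.000352, adjusted p = 0.0707 with an estimated correlation), and hypoxia genes 0.65 and 0.06 (camera adjusted p = 0.00595, adjusted p = 0.0707 with an estimated correlation). Melanocyte genes had medians of -0.21 and 0.03 (camera adjusted p = 0.0276, adjusted p = 0.105 with an estimated correlation), and collagen genes 0.15 and 0.68 (camera adjusted p = 0.0438, adjusted p = 0.788 with an estimated correlation, and 0.11 after removal of the length trend, which also brought the Wnt feedback targets from 0.202 to 0.0376).

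Gli2 RNA was higher in the libraries labelled Gli2 knockout than in Cas9-NTC. Counting noise was argued against, since the lowest interval bound of the former was 1.52 times the highest of the latter. Reads of the related gene Gli3 counted as Gli2 were argued against too, since the Gli3 level of NTC would give 0.867 FPKM of Gli2 there, against a limit of 0.0272. An exchange of the labels of the Cas9 groups cannot be told apart from the labels as given by the pathway target Gli1, whose pooled read rate had a ratio of 1.38 (95% interval 0.802 to 2.40, from 35 and 25 reads), although the 237 genes at least 2-fold higher in Gli2CA had a median log2 change of -0.29 in the libraries labelled Gli2 knockout and 75.1% of them were lower, against 51.0% of all genes. A coding change that leaves the RNA in place stays open and was not tested, because the values hold no sequence.

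Library 3 labelled Gli2 knockout lay 2.05 times as far from the other members of its group as the most distant library elsewhere, and 73.3% of the 1024 genes called by 2-fold without it were on the same side in it. Both changes were taken from the same Cas9-NTC libraries, which favours agreement. At these genes library 3 lay a median of 85.3% of the way in FPKM from libraries 1 and 2 to Cas9-NTC. Of the 26 genes that parted libraries 1 and 2 from Cas9-NTC by 4-fold, 19.2% lay nearer Cas9-NTC in library 3. Across all genes, log2 changes without library 3 and without libraries 1 and 2 correlated at 0.362. A length trend as the whole cause was argued against, since the ratio of distances stayed at 1.79 after its removal, and a swap with a Cas9-NTC library was argued against by the most distant of these, at 0.327 of the distance of library 3. Against a mixture with Cas9-NTC cells, 4 genes abundant in Cas9-NTC and nearly absent from libraries 1 and 2 reached a median of 2.22% of their Cas9-NTC level in library 3, where a mixture would need 85.3%, with Pdpn at 0.111% and Gm4825 at 0. That test replaced earlier versions, the first of which went with a mixture, since 9 genes lay 2-fold beyond all 5 other libraries in library 3 (13 and 6 in libraries 1 and 2), and the second had too few genes to decide, so the exclusion rests on limits set after those outcomes were known and mainly on Pdpn and Gm4825. The groups name no biological difference between these 3 libraries, so none was tested, and separately derived cells or another outside sample stay open.

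The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d were 3.96, 3.44, 3.17 and 2.79 times as high in Gli2CA as in NTC, here as ratios of geometric means. Scaling or depth was argued against by the median log2 difference of all genes, 0.00344. Cells of the Cas9 line in the Gli2CA cultures were argued against by 28 genes abundant in that line and nearly absent from NTC. These reached a median of 1.36% of their Cas9-NTC level in Gli2CA (at most 11.6%), where Ddx3y would need 66.8%. The needed share was computed for Ddx3y alone. The limits for the 28 genes were widened after a stricter choice had left too few. A larger share of NTC cells without the Y chromosome stays open, and it predicts 1 common ratio for the 4 genes. Their log2 ratios differed by up to 0.502, or 2.96 standard errors. That lay just inside a bound of 3 set after the results were seen, so the test does not decide. No biological explanation is named by the groups, and the share of cells was not measured. These tests concern NTC and Gli2CA only. In the libraries labelled Gli2 knockout, Ddx3y, Uty and Kdm5d were called lower than in Cas9-NTC (log2 changes -0.42, -0.52 and -0.26, limma adjusted p = 0.0204, 0.00289 and 0.0341). Eif2s3y was not called there (-0.20, limma adjusted p = 0.292). Ddx3y, Uty and Kdm5d are thus among the 460 genes higher in Gli2CA and lower in those libraries.

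Over the 10 splits of the 6 libraries of a comparison, a share under 0.05 cannot be reached, and 1 split, the real one, gave each result. The real values and the highest of the other splits were 1685 and 1 genes for Gli2CA and NTC, 275 and 1 by 2-fold, 5798 and 0 for the control lines, and 10 and 7 for the lists. For the libraries labelled Gli2 knockout and Cas9-NTC they were 3182 and 2107 genes, 333 and 71 by 2-fold, and 5 and 4 lists. The split with 2107 genes set libraries 1 and 2 labelled Gli2 knockout and Cas9-NTC library 1 against the rest, which points to the structure of that group. For the difference between the changes and for the genes with opposite signs, 1 of 100 splits, the real one, gave as many genes (3356, highest other 1603, and 620, highest other 96). Splits that mix the groups put the group differences into the spread between libraries, which lowers their counts. These values therefore do not exclude chance.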

How the results depend on the processing

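The removal of the length trend, voom and the fit without libraries 1 and 2 labelled Gli2 knockout were chosen after seeing the data, and the other alternatives were planned. Between Gli2CA and NTC, limma called 2916 genes in a fit of these groups alone, 4445 with library weights and 968 at an adjusted p under 0.01, against 1685. The 275 genes changed by 2-fold became 611 and 69 with pseudocounts of 0.1 and 5, 437 after rescaling to a common total and 592 with voom. Between the libraries labelled Gli2 knockout and Cas9-NTC, the 3182 genes became 762 in a fit of these groups alone, 9158 with library weights, 1139 at an adjusted p under 0.01 and 1595 without libraries 1 and 2. The 333 genes changed by 2-fold became 673 and 86 with pseudocounts of 0.1 and 5, 633 after rescaling, 815 with weights and 787 with voom. The difference between the changes gave 8488 genes with weights and 1687 at an adjusted p under 0.01, against 3356, and the genes with opposite signs 2286 and 272, against 620. Genes with the same sign in both comparisons were 1138 and 28 under these settings, against 96. The share of opposite signs was 66.8% and 90.7%, against 86.6%. With an estimated correlation 5 of the 10 lists of Gli2CA and 0 of the 5 lists of the libraries labelled Gli2 knockout were called, and for the latter fry called 11 and an adjusted p under 0.01 left 3. Without libraries 1 and 2, the collagen list (adjusted p = 0.252) and Wnt7b (log2 change 0.39, adjusted p = 0.0173) turned direction with a call in 1 of the fits, and Ptch1 (adjusted p = 0.392) and Wnt5a (adjusted p = 0.552) turned with a call in neither. Thresholds and pseudocounts change the counts by their construction, and otherwise the cause was not tested.

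Leaving out 1 library in turn gave 1132 to 1346 genes for Gli2CA (265 to 301 by 2-fold), 1338 to 7793 for the libraries labelled Gli2 knockout (240 to 1024 by 2-fold), 2373 to 7535 for the difference, 389 to 1770 with opposite signs, 5058 to 5281 between the control lines, 10 to 11 lists for Gli2CA and 4 to 6 lists for the libraries labelled Gli2 knockout. Both 7793 and 1024 came without library 3 and 240 without library 1. Of the list results over all alternatives, 388 kept their side of the threshold for Gli2CA, 13 passed it and 10 lost it, and 390, 22 and 16 did so for the libraries labelled Gli2 knockout. Of the named gene results, 1580, 7 and 59 did so for Gli2CA and 1556, 9 and 120 for the libraries labelled Gli2 knockout. All 127 kept theirs between the control lines. Depth limits low genes: Hhip, Cxcl2, Cxcl5 and Wnt11 had at most 2, 4, 5 and 14 reads in a library, and Gli2 and Gli1 0 to 345 and 4 to 120.

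Replicate numbers do not pair the libraries: same-numbered libraries had correlations of 0.10, 0.01 and -0.05 in the first experiment and 0.25, -0.15 and 0.20 in the second. With the replicate number as a block, 1290 and 3073 genes were called in the main comparisons (280 and 335 by 2-fold), 3006 for the difference, 464 with opposite signs and 4340 between the control lines, with 11 and 5 lists. Among lists the block changed the call of the neural-crest-like list in Gli2CA alone (adjusted p = 0.0425). Among named genes it ended the calls of Ifit3 (0.0874), Ifit1 (0.0739), Thbs1 (0.0884) and Ivl (0.0636) in Gli2CA, and of Ccl5 (0.0632) and Ccnb2 (0.0525) in the libraries labelled Gli2 knockout. In each experiment 1 of the 3 control libraries correlated best with its own number, and the labels give no shared culture or day for a number.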

Other observations

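The test of chromosome copies was chosen after the result had been seen. Genes of chromosome 15 were higher in Cas9-NTC than in NTC, with a median log2 difference of 0.58 over 482 genes and 77.4% of them higher. The medians of the other numbered chromosomes lay between -0.27 and 0.14. Within the Cas9 line the same genes had a median of -0.12 in the libraries labelled Gli2 knockout, and in Gli2CA they had one of 0.00 against NTC. A hypothesis is that the lines may differ in copies of the whole chromosome, which predicts a shift along all of it. With each chromosome split into 4 parts of equal gene number, the medians along it were 0.62, 0.62, 0.60 and 0.46, and the lowest, 0.461, exceeded the highest of any part of the other numbered chromosomes, 0.239. The 4 parts of chromosome 16 had medians of -0.261, -0.209, -0.258 and -0.448. A shift along a whole chromosome was thus not particular to chromosome 15, and the last of these was of like size. DNA was not measured, and the groups name no such difference.

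Gli3, which encodes the related Hedgehog factor that mainly represses, averaged 1.71 ± 0.0697 FPKM in NTC and 1.21 ± 0.123 in Gli2CA, and 2.27 ± 0.217 in Cas9-NTC. In the libraries labelled Gli2 knockout it lay at 1.62, 1.65 and 3.87 FPKM in libraries 1, 2 and 3. The gene was chosen after its values were seen, as a check on reads shared with Gli2.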
